A study of Catostomus macrocheilus with 21 samples.

How the data were processed

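Liver RNA of 21 wild largescale suckers (Catostomus macrocheilus), a bottom-feeding freshwater fish, was measured on 1-colour Agilent arrays. Each array held the RNA of 1 fish. Per the labels, the fish were reproductive adults from 3 collection sites on the Columbia River, with 6 fish from Columbia City, 7 from Longview and 8 from Skamania. The labels give no sex, size or contaminant level for a fish, so none entered a test.

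Per the labels' protocols, total RNA was treated with DNase, purified on columns, and labelled with Cy3 as cRNA. Per the submitters' processing notes the scans were read with Agilent Feature Extraction 9.1, whereas the file headers name version 10.1.1.1; the files alone do not settle which is right. The authors' deposited scanner files hold linear spot intensity values, and the main values were the processed signals in them. Per the file headers an Agilent 1-colour protocol was used; how it treated background is not given in the sources used here. Each array carried 15208 non-control spots and 536 control spots. The non-control spots represent 14758 probes, of which 14708 were printed once and 50 were printed 10 times. No non-control spot was saturated. A second deposited table holds the authors' log2 values of the same arrays. Its columns had a common median of 6.10 and followed the log2 processed signals of their own arrays, with 117 missing values, all at spots flagged as non-uniform, so its scale is log2 and it was not centred by gene. The labels do not name the step that equalised its columns. At 99 percentiles the columns differed by at most 0.000242, and each correlated by at least 0.9999 with the log2 processed signals of its array after quantile normalization, so quantile normalization is read from the values.

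For each array, log2 processed signals were averaged over the spots of a probe, leaving out 555 spots with outlier flags among the 319368 spot values, and the 75th percentile of the array was subtracted. Levels below are on this scale, so 0 is the 75th percentile of the probes on an array. A probe was tested if it was well above background on at least 6 of 21 arrays, which kept 11040 probes, or 74.8%. A further 1509 probes were well above background on no array. Site means were compared with limma 3.58.1 in R 4.3.3, with 1 mean per site and 18 residual degrees of freedom. The 3 pairwise differences and a moderated F test over the 3 sites were each adjusted by the Benjamini-Hochberg method over all probes tested, and probes with an adjusted p under 0.05 are called. All limma tests were two-sided. Figures were drawn with matplotlib 3.10.9. Site differences in array measures were tested with two-sided exact permutation tests, adjusted over 18 tests. Where no array of a group measured a probe well above background, the fold is given as "at least": the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Such a bound carries no sampling error and applies to the main processing only.

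Each slide was scanned once, so slide and scan are one factor. Slide 1 held 1 Columbia City, 2 Longview and 3 Skamania arrays, slide 2 held 3, 3 and 2, and slide 3 held 2, 2 and 3. Among the 33 probes printed 10 times and well above background on all 21 arrays, the median SD between spots of an array was 0.0870 on the log2 scale, against a median SD of 0.672 between fish of a site. For these 33 the number of arrays, more than that of spots, limits the precision. With 1 array per fish, the SD between fish also holds differences between arrays. Spot noise of dim probes printed once was not measured. The fit was tested on simulated data for 11040 probes. For Longview against Skamania it called 10.0% of probes changed 1.5-fold, 40.0% of those changed 2-fold, 82.0% at 4-fold and 98.0% at 8-fold. For Columbia City against Skamania the shares were 4.00%, 26%, 68.0% and 96.0%.

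The groups, tests, filters and most alternatives were fixed before the data were examined. The alternatives covered quantile normalization, median centring, other filters on dim probes, slide as a fixed or random block and within each slide, array row, a replicate block, fits of 2 sites, another prior, array weights, other thresholds, the authors' deposited log2 values, and leaving out each array in turn. Alternatives added after seeing the data were normexp on median signals with an offset of 50 (the mean signals first planned for it were not used here), the first principal component or the signal of either of 2 control probes as a covariate, no scaling between arrays, flagged spots kept, the second principal component with brightness removed, and brightness classes with no filter. Comparisons that share the Skamania arrays were set against 100 reassignments of the residuals to the sites.

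The files used here pair probes with sequence names and not with gene names. The gene lists, marker lists and named genes chosen beforehand could therefore not be matched to probes, and no pathway or cell type was tested. In their place, the probes past the threshold with the largest differences are given by ID for Longview against Skamania, 2 in each direction.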

Results

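The series measured liver gene expression in 21 wild largescale suckers from 3 sites of the Columbia River, in a study of contaminant exposure. The design set 6 fish from Columbia City, 7 from Longview and 8 from Skamania against each other. Between 8179 and 11806 of the 14758 probes were well above background on an array. The mean was 10600 ± 832 (SD, n = 7) at Longview, 9695 ± 714 (SD, n = 6) at Columbia City and 9655 ± 843 (SD, n = 8) at Skamania, and the difference of Longview from Skamania did not pass correction (exact permutation p = 0.0491, adjusted 0.182 over 18 tests). The correlation between 2 arrays ranged from 0.826 to 0.959.

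The first question was whether liver expression differed among the sites. By the limma F test, 194 of 11040 probes differed at an adjusted p under 0.05, and 185 of them were also called between Longview and Skamania. Without Columbia City replicate 6 the count was 343, and without Longview replicate 1 it was 128. It was 0 after normexp background correction and 5 among probes well above background on at least 11 arrays.

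The Longview and Skamania arrays differed mainly in dim probes that were higher at Longview. By limma, 313 of 11040 probes were called, of which 300 were higher at Longview and 13 were lower. The higher probes had a median log2 difference of 1.91, with a range from 0.59 to 3.57. Their median processed signal was 14.4 units, and 253 of the 300 lay at or below 32 units, a class that held 2159 of the probes tested. On the Skamania arrays, 146 of the 300 were never well above background, and their bounds had a median of at least 3.11-fold. All 146 bounds lay above 1. That is no separate evidence, since such probes passed the filter through the other sites and were chosen as higher at Longview. The Longview and Skamania ranges did not overlap for 170 of the 300 higher probes. Over all probes tested this was so for 202, where chance gives 3.43, or 0.0311%.

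Of the higher probes, LSS_UF_10309 had the largest fitted difference, although the order among probes with only a bound at Skamania is not determined. Its level was -3.0 ± 0.42 (SD, n = 7) at Longview, where all 7 arrays were well above background, and -6.57 ± 0.82 (SD, n = 8) at Skamania, where 1 of 8 was. The log2 difference was 3.57 with an SE of 0.55 (limma adjusted p = 0.00106). LSS_UF_18666 was at -3.46 ± 0.35 (SD, n = 7) at Longview and was not well above background on any Skamania array. On this scale the bound between the means was at least 4.89-fold, and its fitted difference was called (limma adjusted p = 0.00249). The bound has no interval and holds only for this processing. At Columbia City, 1 of 6 arrays was well above background for each of these probes. There LSS_UF_10309 stood at -2.09 in replicate 6, against -7.24 to -5.67 in the other 5 fish. Under 3 alternatives chosen after seeing the data, neither was called. The difference of LSS_UF_10309 was then 1.13 with an SE of 0.26 with normexp (limma adjusted p = 0.248), 1.59 with an SE of 0.53 with the control probe ETG10_234183 as a covariate (0.276), and 1.72 with an SE of 0.56 with the control probe E1A_r60_a104 (0.0701). The fitted differences of LSS_UF_18666 are not exact sizes, since no Skamania array was well above background. They were 3.16 with an SE of 0.57 in the first fit, and 0.85, 1.62 and 0.90 in these 3 alternatives. Their SEs were 0.27, 0.69 and 0.46 (limma adjusted p = 0.367, 0.381 and 0.236).

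The 13 probes lower at Longview were brighter, with a median processed signal of 372 units, and were a median of 2.15-fold lower. Of these, 11 were well above background on all 21 arrays. LSS_UF_24050 had the largest difference, -6.53 with an SE of 1.68 (limma adjusted p = 0.0350), and its Longview values were split. In Longview replicates 3, 4, 6 and 7 its level lay between -5.51 and -3.47, and in replicates 1, 2 and 5 it lay between 3.56 and 7.62. The other 14 fish ranged from 1.90 to 7.62. The 4 low Longview fish were on slides 2 and 3, and the difference within slides 1, 2 and 3 was -0.16, -8.96 and -9.94 (limma adjusted p = 0.971, 0.356 and 0.417). The call was lost in 11 of the 21 fits that left out 1 array. LSS_UF_12363 was at -5.23 ± 0.57 (SD, n = 7) at Longview, where 2 of 7 arrays were well above background, and -2.96 ± 1.21 (SD, n = 8) at Skamania. The log2 difference was -2.27 with an SE of 0.55 (limma adjusted p = 0.0238), and the call was lost in 4 of those 21 fits. At Columbia City it was at -5.24 ± 1.47 (SD, n = 6), near the Longview level, with 1 of 6 arrays well above background. Columbia City replicate 6 stood at -2.47, against -6.64 to -4.86 in the other Columbia City fish. With the replicate number as a block, the adjusted p was 0.0652 for LSS_UF_24050 and 0.0686 for LSS_UF_12363. With normexp, and with ETG10_234183 or E1A_r60_a104 as a covariate, LSS_UF_24050 was not called. Its differences were -5.03, -6.26 and -7.45, with SEs of 1.31, 2.47 and 2.45 (limma adjusted p = 0.312, 0.350 and 0.0701). With normexp, the difference of LSS_UF_12363 was -0.27 with an SE of 0.33 (limma adjusted p = 0.717). With ETG10_234183 as a covariate it was -3.43 with an SE of 0.73 (0.167), and with E1A_r60_a104 it was -3.99 with an SE of 0.60 (0.00295).

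**Figure D1:**
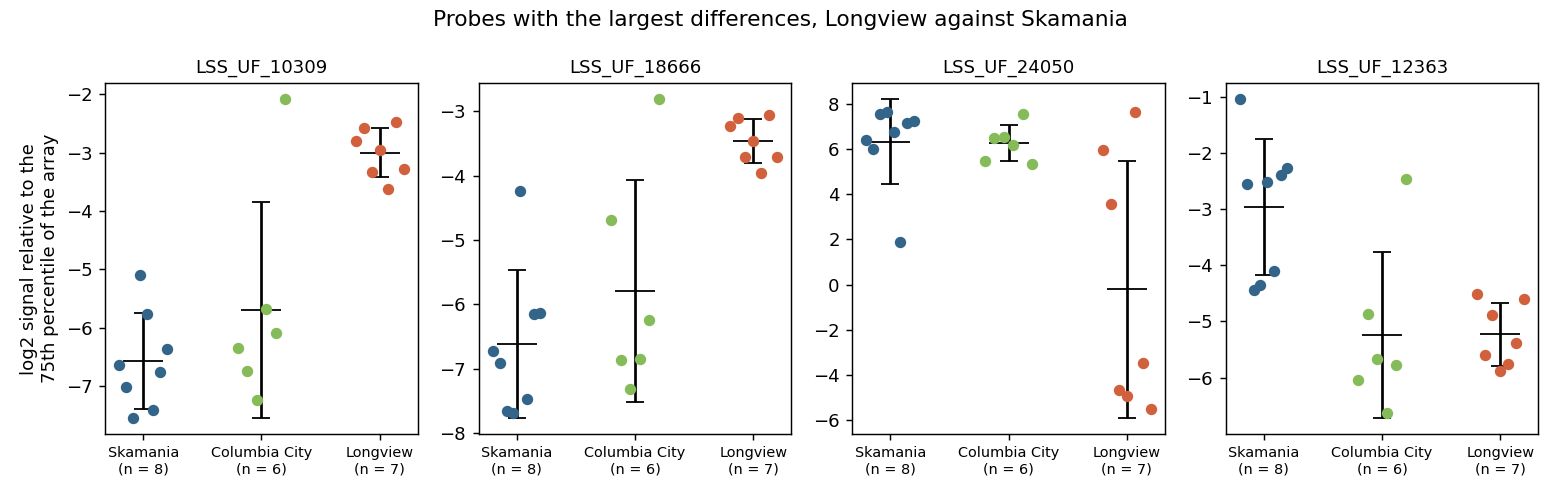
Levels of 4 probes in single fish, as log2 signal relative to the 75th percentile of the array, by site. Points are fish, and the line and bars are the mean and SD; LSS_UF_24050 takes separate low and high levels among the 7 Longview fish.

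The Longview difference varied with probe brightness among probes that passed the filter. Among the 704 tested probes with a mean signal between 8 and 16 units, the median log2 difference between Longview and Skamania was 0.69 and 161 probes were called higher. Among the 2440 probes between 256 and 1024 units the median was 0.02, and 5 were called higher and 4 lower. The gradient was not particular to Longview, although both differences share the Skamania arrays. For Columbia City minus Skamania the median was 0.38 between 8 and 16 units and 0.16 between 32 and 64 units. Longview minus Columbia City had medians of 0.47 and 0.004 in these classes, and Longview minus Skamania one of 0.17 in the second. Signals on the Longview arrays alone can bring a dim probe past the filter, which raises the medians of dim classes. With no filter, the median for Longview minus Skamania between 8 and 16 units was 0.55 over 1686 probes, and 0.03 over the 2736 probes below 8 units. With classes set on the Columbia City arrays alone and no filter, chosen after seeing the data, these medians were 0.46 and 0.12, and it was 0.03 between 256 and 1024 units. Of the 7072 probes well above background on all 21 arrays, 21 were called higher and 11 lower, and 1 was called when only these probes were tested. After normexp with an offset of 50, which compresses dim signals, 1 probe was called in all. The median log2 difference of the 300 was then 0.65, with a median SE of 0.26, against 1.91 with a median SE of 0.39 in the first fit. Quantile normalization gave 168 calls, with 151 higher, all among the 300, and 17 lower, of which 10 were among the 13. With slide as a fixed block the median log2 difference of the 300 probes was 1.92. Within slides 1, 2 and 3 it was 1.88, 2.06 and 1.61, although no probe was called within a slide.

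**Figure D2:**
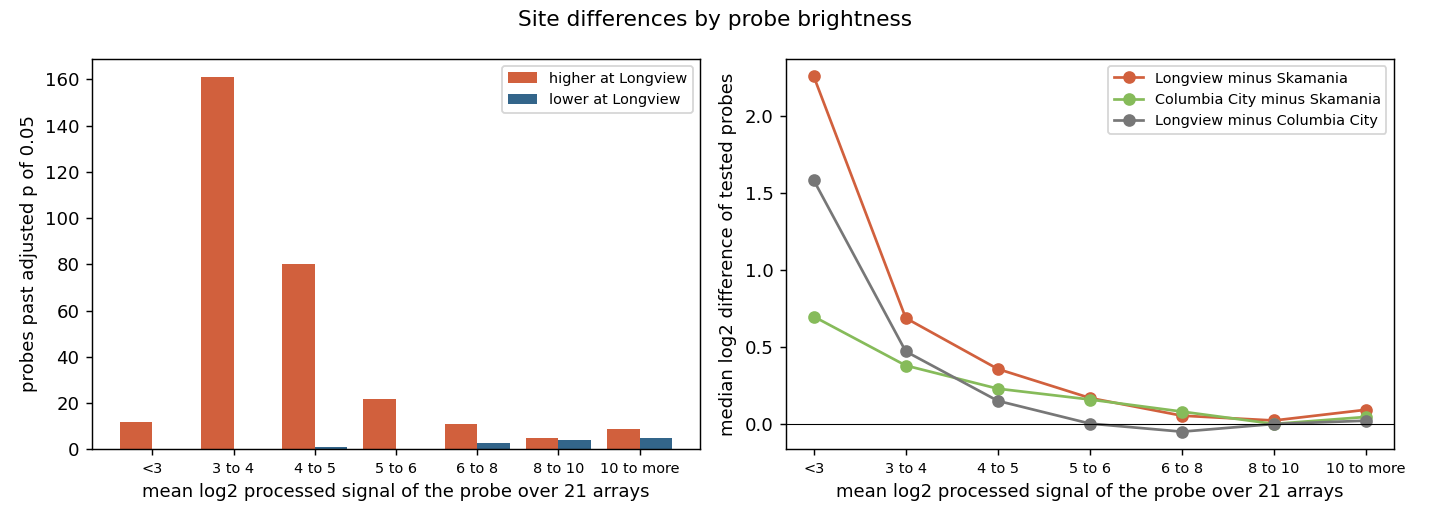
Left, probes called between Longview and Skamania, and right, the median log2 difference of all tested probes, both by the probe's mean log2 processed signal over 21 arrays. The median for Longview minus Skamania falls from 0.69 at log2 signals of 3 to 4 to 0.02 at 8 to 10, and that for Columbia City minus Skamania from 0.38 to 0.002. The lowest class holds 14 probes, and dim classes hold only probes that passed the filter, which Longview signals alone can meet.

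Control spots, which are not designed to measure fish transcripts, also differed between these sites before scaling. Of 60 control probes, 2 were called by limma, both higher at Longview, and 7 had an unadjusted p under 0.05. Other dim control probes, E1A_r60_3 and eQC-41, differed by 0.61 and 0.67 (limma adjusted p = 0.182 for both), and the negative control probe by -0.12. The brighter spike-in probes E1A_r60_a135 and E1A_r60_a20 differed by -0.01 and -0.07. The control probe ETG10_234183 had a log2 signal of 3.49 ± 0.44 (SD, n = 7) at Longview and 2.29 ± 0.29 (SD, n = 8) at Skamania (limma adjusted p = 0.00410). Its Skamania level was near the 2.19 ± 0.23 (SD, n = 8) of the negative control probe, so the sizes of its differences are not exact. The dim spike-in probe E1A_r60_a104 was at 5.13 ± 0.27 (SD, n = 7) and 4.20 ± 0.38 (SD, n = 8), with the same adjusted p. After scaling to the 75th percentile none of the 60 was called by limma, and 2 had an unadjusted p under 0.05, but the differences stayed close to those before. For ETG10_234183 the difference was 1.199 (95% interval 0.67 to 1.72) before scaling and 1.12 (0.44 to 1.80) after it (adjusted p = 0.0985), and for E1A_r60_a104 it was 0.92 (0.50 to 1.34) and 0.84 (0.13 to 1.56, adjusted p = 0.662), so the calls ended with wider intervals. With ETG10_234183 as a covariate, a choice made after seeing the data, 0 probes were called between Longview and Skamania, 1299 had an unadjusted p under 0.05, and the median log2 difference of the 300 probes was 1.17. With E1A_r60_a104 as a covariate, chosen in the same way, 350 probes were called higher and 376 lower, 42 of the 300 were still called, and the median log2 difference of the 300 was 1.02. Since both control probes differ between these sites, either covariate also takes up part of any site difference. The median SE of the 300 was 0.50 with ETG10_234183 and 0.44 with E1A_r60_a104, against 0.39 in the first fit. These fits therefore cannot tell an effect on control spots from a difference between the sites.

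**Figure D3:**
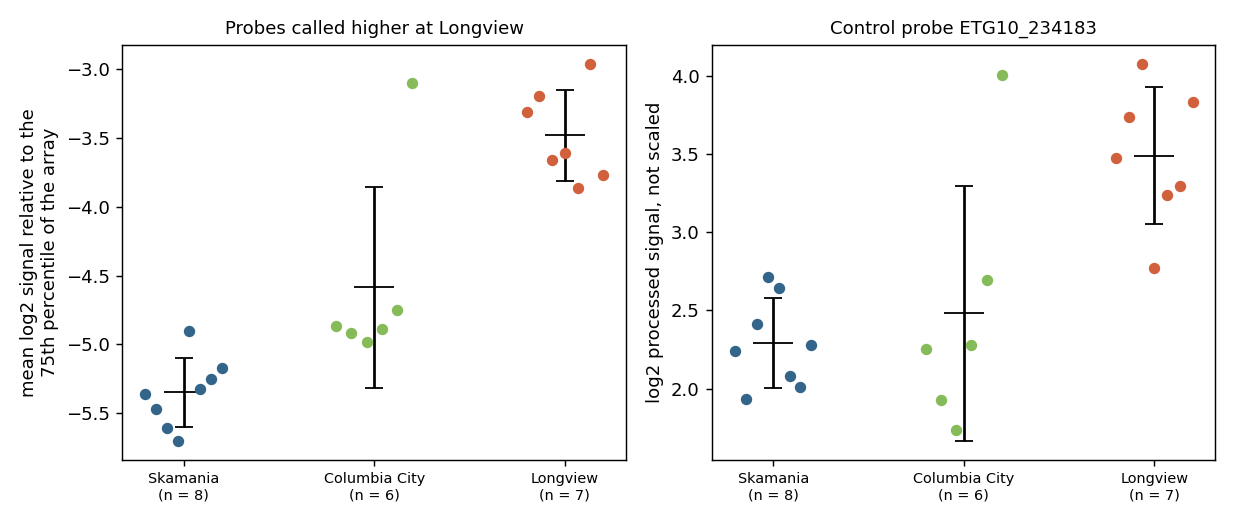
Left, the mean level of the 300 probes called higher at Longview than at Skamania, which were chosen for that difference, and right, the unscaled log2 signal of the control probe ETG10_234183, per fish. Lines and bars are the mean and SD; Columbia City replicate 6 stands at -3.10 and 4.01, within the Longview range in both.

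Between Columbia City and Skamania no probe was called by limma. An unadjusted p under 0.05 was found for 1022 of 11040 probes, or 9.26%, and the smallest adjusted p was 0.0631. The count was 11 with array weights and 1 without Columbia City replicate 1 or without Skamania replicate 6. In simulated data this comparison recovered 26% of 2-fold changes, so smaller differences were mostly not detectable with these numbers of fish. On the second principal component, with 9.87% of the variance, Columbia City had a mean of 14.4 ± 13.8 (SD, n = 6) and Skamania one of -20.2 ± 24.0 (SD, n = 8), a difference that passed correction (exact permutation p = 0.00733, adjusted 0.0440 over 18 tests). This component also followed array brightness, the log2 75th percentile, across the 21 arrays (Pearson's r = -0.656, permutation p = 0.000970, adjusted 0.00291 over 3 components; Spearman's rho = -0.540, permutation p = 0.0122). With its linear relation to brightness removed, a step chosen after seeing the data, the means were 5.13 ± 13.4 (SD, n = 6) and -17.9 ± 17.7 (SD, n = 8), with an exact permutation p of 0.0270 that was not adjusted.

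Between Longview and Columbia City no probe was called by limma either. An unadjusted p under 0.05 was found for 1092 of 11040 probes, or 9.89%, and the smallest adjusted p was 0.158. Without Columbia City replicate 6, 188 probes were called higher at Longview and 3 lower. With all fish, 79 were called with array weights and 104 with no scaling between arrays. Before scaling, the same 2 control probes were called here, by 1.01 for ETG10_234183 and 0.86 for E1A_r60_a104 (limma adjusted p = 0.0357 for both). Outside replicate 6, ETG10_234183 was at 1.73 to 2.69 at Columbia City. The negative control probe was at 2.13 ± 0.42 (SD, n = 6) there, so the 1.01 is not an exact size. After scaling the differences of the 2 control probes were 0.62 and 0.48 (adjusted p = 0.604 for both). On the third principal component, with 9.36% of the variance, Longview had a mean of -32.5 ± 16.4 (SD, n = 7), against 15.4 ± 17.1 (SD, n = 6) at Columbia City (exact permutation p = 0.00175, adjusted 0.0157) and 16.9 ± 14.4 (SD, n = 8) at Skamania (exact permutation p = 0.000155, adjusted 0.00280). Its r with array brightness was -0.436 (permutation p = 0.0489, adjusted 0.0489 over 3 components), with Spearman's rho at -0.373 (permutation p = 0.0975).

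The differences of Columbia City and Longview from Skamania were compared, and both use the Skamania arrays, which alone can make them alike. Across 10956 probes, which are not independent replicates, the log2 differences correlated with r = 0.547. Reassigned residuals with no site effect gave a median of 0.427 and a central 95% range from 0.0614 to 0.708. The covariance was 0.168 against 0.0793 in the reassignments, whose range was 0.0138 to 0.233, so neither value lay outside what the shared arrays give with no site effect. With the Skamania fish split at random into 4 and 4, 1 set for each difference, the median r was 0.199. With no called probe at Columbia City, the overlap of calls was 0.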

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

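The control-spot, slide and background tests below, and those of the first principal component, were chosen after the result was seen, and the control-spot test was revised once its first form, with brightness not removed (r = 0.817 for ETG10_234183), had been seen; the first test of a wrong label and the counts of splits were set beforehand, and the tests of a wrong label with probes chosen anew and by the third principal component came after. Of 45 groups of values examined for a fish far from the others, 4 had one, and chance alone gives about 1 in 20.

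Of 100 splits of the Longview and Skamania arrays, 1, the real one, gave as many as 313 called probes, and the highest of the others gave 2. A random division of these arrays is thus an unlikely source of that count. The splits cannot tell site from another factor that differs between the same arrays. Likewise 1 of 100 splits of all 21 arrays gave as many as 194 probes by the F test, with 1 probe in the highest of the others. For probes at an unadjusted p under 0.05, chance could not be excluded in the other comparisons: 8 of 100 splits gave at least the 1022 probes of Columbia City against Skamania (highest other 1918), and 11 of 100 gave at least the 1092 of Longview against Columbia City (highest other 1745).

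The 300 probes higher at Longview make up most calls, and 253 of them lay at or below 32 units. The negative control probe had a scaled log2 difference between Longview and Skamania of -0.20 (95% interval -0.87 to 0.48), far from the 1.91 of the probes. This argues against a uniform rise of the processed signals. It cannot decide on a rise of raw background, since how the protocol treated background is not given. Slide is argued against by the fit with slide as a fixed block, set beforehand, which called 307 probes, 296 of them higher at Longview. The median difference was at least 1.61 within every slide, but the 300 probes were chosen on these same arrays. A factor of single RNA or labelled samples that also acts on control spots cannot be told apart from the sites, and a biological difference between the sites stays open too. With site means and array brightness removed, the mean of the 300 probes followed ETG10_234183 (r = 0.846, permutation p = 0.00182, adjusted 0.00728 over 4 relations; rho = 0.662, permutation p = 0.00247), and r was 0.525 without the 2 farthest arrays and 0.551 without Columbia City replicate 6, but the mean scaled to the 75th percentile gave r = 0.635, and 0.0370 without that fish. For E1A_r60_a104, r was 0.749 (permutation p = 0.0218, adjusted 0.0435), 0.288 without Columbia City replicate 6 (permutation p = 0.268), and 0.352 with brightness not removed (permutation p = 0.210), but the mean scaled to the 75th percentile gave r = 0.784, and 0.538 without that fish. The bright corner control gave r = 0.145 (permutation p = 0.344, adjusted 0.458), but 0.539 without that fish (permutation p = 0.0363). With the scaled mean these were 0.0230 and 0.146. The negative control probe gave r = 0.0932 (permutation p = 0.704, adjusted 0.704), and 0.264 without that fish (permutation p = 0.224). Without that fish the relation was thus not particular to ETG10_234183.

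Columbia City replicate 6 was far from the other Columbia City fish in the mean level of these 300 probes, whose choice Columbia City values entered through the shared residual spread and the filter, at -3.10 against -4.98 to -4.75, and in LSS_UF_10309, at -2.09. A Longview fish under a Columbia City label stays open: the median level of the 13 probes lower at Longview was 0.0520 in this fish, above the Longview range of -1.24 to -0.30, which met the bound set beforehand, but those probes were chosen for low values in the same Longview fish, and 2 of the other 5 Columbia City fish lay inside that range. Among the 13, LSS_UF_12363 stood at -2.47 in this fish, above its Longview range of -5.89 to -4.51 and above the other Columbia City fish. LSS_UF_24050 stood at 5.33, inside its Longview range of -5.51 to 7.62. Then 13 probes were chosen each time without Columbia City and without the Longview fish measured. Longview medians on these sets ran from -1.22 to 0.92 (95% prediction interval -2.14 to 1.52), and those of this fish from -1.37 to 0.30. In each set the lowest other Columbia City fish and the lowest Skamania fish also lay inside that interval, so it cannot tell the sites apart. The third principal component was computed from 10956 tested probes, so it is not independent of the 300. Longview fish lay from -53.7 to -8.29 on it, all but replicate 4 at -18.4 or below. This fish stood at -13.0, inside that range and outside the 7.12 to 34.4 of the other Columbia City fish. A factor of that RNA or labelled sample that also acts on control spots is a candidate explanation, since ETG10_234183 was at 4.01 there, above the highest of the Skamania and other Columbia City arrays, 2.72. The labels name no condition that sets this fish apart, so no biological explanation was tested.

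LSS_UF_18666 stood at -4.23 in Skamania replicate 5, against -7.68 to -6.14 in the other Skamania fish, and was not well above background in any of them. LSS_UF_24050 stood at 1.90 in Skamania replicate 6, against 6.01 to 7.62 in the others.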

How the results depend on the processing

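Counts of calls are given for Longview against Skamania (313) first and then for the F test (194). They were 168 and 102 with quantile normalization, 170 and 101 with the authors' deposited values, 19 and 5 among probes well above background on at least 11 arrays, 1 and 1 on all 21 arrays, 0 and 0 within each of slides 1, 2 and 3 (fewer arrays), 555 and 437 with array weights, and 500 and 323 at an adjusted p under 0.10. Without a filter on dim probes Longview against Skamania had 544. The stricter filters test fewer probes and leave out most of the dim ones; of the other changes the cause was not tested. Among alternatives added after seeing the data, the counts were 1 and 0 with normexp, 0 and 1 with ETG10_234183 as a covariate, 726 for Longview against Skamania with E1A_r60_a104 as a covariate (350 higher, 376 lower), and 310 for the F test with the first principal component.

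Columbia City against Skamania (0) had 4 calls within slide 1, where 1 Columbia City fish is assumed to vary like the other groups, 1 within slide 3, 11 with array weights, 3 at an adjusted p under 0.10, and, added later, 2 with the first principal component, 1 with ETG10_234183 and 6 with E1A_r60_a104. Longview against Columbia City (0) had 2 within slide 1, 79 with array weights, and, added later, 14 with the first principal component and 104 with no scaling between arrays. Leaving out each array in turn gave 211 to 378 calls for Longview against Skamania, 128 to 343 for the F test, 0 to 1 for Columbia City against Skamania and 0 to 191 for Longview against Columbia City. The correlation of the differences was 0.452 to 0.623 in those fits and 0.199 with Skamania split into 4 and 4. Without scaling, the median log2 difference of all probes was -0.22 for Columbia City against Skamania, 0.19 for Longview against Skamania and 0.41 for Longview against Columbia City, against 0.09, 0.11 and 0.02 with it. None of the 4 named probes changed direction. In every alternative with all 300 higher probes tested, at least 298 kept their direction, but they were chosen for it on the same arrays. Of the 300, 0 stayed called with ETG10_234183 as a covariate, 1 with normexp and 42 with E1A_r60_a104. Both control probes differ between Longview and Skamania, so as covariates they also take up part of any site difference.

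The replicate block gave 258 calls for Longview against Skamania, 170 for the F test, and 0 for both other contrasts, with a correlation of 0.541. The numbers name different fish and do not pair them: the deviations of 19 same-numbered pairs correlated by -0.0283 on average, against 0.00278 for other pairs, and 3 of 21 arrays correlated best with their own number. Of the named probes, LSS_UF_10309 and LSS_UF_18666 each lost the call in 6 of 41 alternatives, LSS_UF_24050 in 20 of 42 and LSS_UF_12363 in 11 of 42. Not run were normexp on mean signals, 1 probe per named gene, and all tests of gene lists. Signal over background limits the dim probes: 146 of the 300 have only a bound at Skamania.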

Other observations

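The tests of the first principal component were chosen after the result was seen, and so was the bound of 50% used to read them, which replaced a comparison with shuffled labels for slide and site and a bound on r for brightness. Some probes varied widely between fish of the same site. Of 10956 probes, 44 ranged over at least 10 log2 units among the 21 fish. LSS_UF_10838 ranged from 11.8 to 143685 processed units. It stood between 7.39 and 8.37 on the scaled log2 scale in Columbia City replicates 1 and 6, and between -5.37 and -2.38 in the other Columbia City fish. At Skamania it was between 7.83 and 8.35 in 5 fish and between -3.66 and -1.32 in 3. The Longview fish were graded, at 7.56 in replicate 2 and between 0.16 and 6.54 in the others. LSS_UF_11822 ranged from 55.2 to 171944 units and ran the other way, at -1.39 in Columbia City replicate 6 and 8.87 in Columbia City replicate 3. Its Longview fish were spread from -2.90 to 8.19. Neither was called by the F test (limma adjusted p = 0.627 and 0.448).

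These 2 probes follow the first principal component, which held 26.4% of the variance, and are among the 8 of the 44 that correlated with it by over 0.8 in size. In all, 492 of 10956 probes did so, 322 positively and 170 negatively. Neither slide nor collection site can be the source of the whole component: 1.57% of its variance lay between slides (shuffled median 7.25%) and 7.39% between sites (shuffled median 7.20%, permutation p = 0.491), with upper ends of the 95% intervals at 14.7% and 28.7%, so a smaller share from either stays open. Array brightness stays open: Pearson's r with the 75th percentile was -0.437 (permutation p = 0.0478; -0.411 without the 2 farthest arrays), while Spearman's rho was -0.200 (permutation p = 0.382), and the upper end of the interval of the shared variance was 53.5% by Fisher's transformation but 45.3% by the method used for slide and site. The labels give no sex, so no other biological explanation was tested.

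A smaller set of probes took separate levels without following that component. In 13 probes the fish were divided by a gap of at least 4 log2 units with at least 3 fish on either side, and 11 of the 13 did not correlate with the component by over 0.8. LSS_UF_17787, singled out after its values were seen, was at -6.16 in Columbia City replicate 5, -6.71 in Longview replicate 2 and -6.74 in Skamania replicate 7, and between 0.45 and 3.33 in the other 18 fish. LSS_UF_24050 was the only one of the 13 called between Longview and Skamania, and none was called by the F test.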
